A study of Homo sapiens with 60 samples.

How the data were processed

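Total RNA of human bronchial epithelial cells from air-liquid interface cultures was sequenced in 60 libraries. Per the labels' protocols, 378 ng of RNA per library went through ribosomal RNA removal and a stranded total RNA kit, with spike-in controls added. All libraries were prepared in 1 batch, sequenced as 3 pools of 20, and read as pairs of 75 bases on an Illumina HiSeq instrument. The labels do not say which library was in which pool, so pool and set could not be set against each other. Per the submitters' processing notes, STAR and DESeq and the genome build GRCh38 were used; their versions, the gene annotation, the counting program and the use of strand in counting are not given in the sources used here.

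The deposited table holds 38 blocks of values stacked on each other, each with the same 65988 Ensembl gene IDs, and a second file gives the library names and titles. The first stacked table holds whole counts of reads per gene and library, as deposited by the authors. The other tables, as deposited by the authors, hold these counts times 1 factor per library, as estimated counts that need not be whole, or counts of a subset of libraries, raw or scaled. There are 18 subsets, of which 12 hold 12 libraries and 6 hold 24. The first table alone entered the tests, so rounding to whole numbers changed nothing. Every column matched the title of 1 library (0 unmatched). Spike-in controls have 0 rows in the table.

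Of the gene IDs, 38793 have a symbol and 27195 have none; the latter hold 0.565% to 1.99% of the counts (median 1.16%) and were left out of library sizes and tests, with an alternative that keeps them. Of all IDs, 46089 have a count in some library, and 56868 are in the GENCODE release 29 annotation of GRCh38, used for positions, exon lengths and overlaps. There are 35199 symbols, of which 1610 belong to several IDs. RN7SK and RN7SL genes hold 0.921% to 5.88% of the counts (median 3.29%).

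Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM size factors, and the quasi-likelihood F test with p-values adjusted by the Benjamini-Hochberg method. Adjusted p-values of genes in the text are from this test unless another is named, and the threshold was 0.05. Log2 levels used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the lists and sets. DESeq2 1.42.0 served as the alternative tool. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the file and drew the plots.

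The design, written before the data were examined, foresaw comparisons of LPS, HDM and their combination with the vehicle, with the set as a block. The labels and the sample sheet name no library's stimulus, so none of these was run, nor the differences of responses between sets. The design named the test over the 6 sets on single libraries as the main result in that case. Each set against the mean of the other sets, the comparison of the 2 forms of title code (counts summed per set, 3 sets against 3), and all comparisons between library blocks in the closing section were added after the files were seen.

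The 24 lists, with 506 entries, were also fixed before the data were examined. They cover cytokines, NF-kB, antimicrobial, interferon, alarmin and type 2, immediate early, growth factor, NRF2, aryl hydrocarbon receptor, unfolded protein, glucocorticoid, cholesterol, pattern recognition, barrier, mucin, proliferation and mitochondrially encoded genes, and markers of ciliated, secretory, basal, squamous, ionocyte, immune and fibroblast or endothelial cells. A list of 32 genes of the response to low oxygen and one of 14 blood cell genes were written after the files were seen. The list medians follow members in log2 from their mean over the sets. CYR61 and CTGF are the file's older symbols of CCN1 and CCN2.

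The rule for named genes takes, per list, the 2 members with the smallest p, and 12 genes whatever their p (IL6, CXCL8, CCL20, CSF3, IL1B, TNF, TSLP, IL33, TLR4, LY96, CD14 and MUC5AC). Between stimuli it also took the 10 largest positive and 5 largest negative changes among genes past the threshold, with a mean log2 CPM of at least 1 and the same direction in 5 of 6 sets; this part was used between blocks. For differences between sets the design named no gene outside the lists, since a single gene can follow a donor's genotype. Its rule for named genes foresaw list medians only between sets, so the single genes named there depart from that rule. Marker genes of cell identity, MCIDAS among the ciliated genes and the blood and immune cell genes were named after their values were seen. Genes that could tell a person's sex, HLA genes, commonly deleted genes and immune receptor segments are in no table of single genes.

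No pair of libraries was identical (0 in each set). The closest of the 45 pairs in a set had a chi-square of 2.20 per degree of freedom over 10418 genes, so no library was counted as a repeat of another. In groups of 10 libraries, the highest and lowest library were tested with Dixon's ratio (critical value 0.466) for totals, the shares of mitochondrial ribosomal RNA, RN7 RNAs, mitochondrially encoded mRNA and IDs without a symbol, the medians of the 24 lists and the 12 fixed genes.

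The scripts were tested on simulated counts drawn from the means and library sizes of the data, with a seeded set of genes changed. The simulated spread came from a fit with set and library block as terms, and no block differences were simulated. The real tests between sets leave block differences in the spread, so the shares recovered for them may be too high. For the test over 6 sets on 14036 genes, 67.2% of genes changed 1.5-fold, 95.5% changed 2-fold and 100% changed 4-fold were recovered, with 5 false calls. For set 1 against the others the shares were 85.1%, 100% and 100%, with 10 false calls. For blocks A and B on 14278 genes they were 74.6%, 97% and 100%, with 15 false calls. An added trend with gene length (Spearman 0.826 across genes) fell to 0.004 after the length correction, which subtracts from each library a lowess curve (span 0.3) of log2 level on log2 exon length before limma. The alternatives tried are DESeq2 and its size factors, no filter, other threshold rules, IDs without a symbol, no mitochondrial ribosomal and RN7 genes, the library block as a term, and, between blocks, single libraries, no set term, length correction and leaving out each set.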

Results

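RNA sequencing counts were analysed for 60 libraries of human bronchial epithelial cells grown at an air-liquid interface, a culture form in which basal cells give rise to a layer with ciliated and secretory cells. The labels place the libraries in 6 culture sets of 10, and the libraries of a set share a code in their titles. Per the labels' protocols, cultures spent 20 h in a minimal medium and then received 250 µl of liquid on the apical side for 4 h. It held lipopolysaccharide (LPS, a part of the bacterial outer membrane) at 10 µg/ml, house dust mite (HDM) extract at 25 µg/ml, both of these, or the vehicle. The labels used here do not say which library received which liquid, so the stimuli within and between sets are unknown here, and no comparison of LPS or HDM with the vehicle was made. The comparisons are those between the 6 sets. The labels do not say what a code stands for or which libraries came from separate cultures. The p-values therefore measure the spread between the libraries of a set, which may be technical in part. That spread also holds any differences between stimuli and between the library blocks of the closing section. Over these blocks 6672 of 15837 genes differed, and the main test does not take such differences out.

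Total counts ranged from 8631772 to 16883849 per library, with a median of 12656522.5. The RNAs of the mitochondrial ribosome took 38.5% to 59.2% of the counts (median 46.3%). Without them, 4856942 to 9148282 counts remained per library. Their share was 42.5% ± 2.27 in set 1, 46.3% ± 2.89 in set 2, 44.1% ± 1.59 in set 3, 48.1% ± 3.04 in set 4, 49.8% ± 4.45 in set 5 and 51.4% ± 3.02 in set 6 (SD, n = 10 each). Between 22654 and 27163 genes had at least 1 count in a library. Levels are given below as CPM, counts scaled to library size, after normalisation by edgeR's trimmed mean of M values.

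Genes of airway epithelium were among the most abundant. BPIFA1, a secreted airway defence protein, had a median of 4818 CPM over the 60 libraries, SLPI, a protease inhibitor of airway mucus, 4529, PIGR, the receptor that carries IgA across epithelia, 3356, and BPIFB1, another secreted defence protein, 2921. Basal cell keratins were present in all libraries, with KRT5 at a median of 331 CPM (118 to 779) and KRT15 at 323. FOXJ1, the transcription factor of motile ciliogenesis, had a median of 33.3 CPM (4.43 to 75.4), and SCGB1A1, the club cell secretory protein, 65.4. The adhesion protein of epithelia, CDH1, stood at 295 CPM.

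Genes of blood and immune cells were low, although the sample sheet deposited with the counts gives the tissue as whole blood. Among 14 blood cell genes listed after the files were seen, the globins HBA1 and HBA2 did not exceed 0.0868 and 0.158 CPM in any library. HBB had a median of 2.34 CPM and PPBP, a platelet chemokine, 0.563. The pan-leukocyte gene PTPRC reached at most 0.308 CPM. CD2, C1QA, TPSAB1, CPA3 and NKG7, markers of T cells, macrophages, mast cells and natural killer cells, had 0 counts in all 60 libraries. Of 15 fibroblast and endothelial markers, KDR stood highest, with a median of 89.1 CPM, followed by FBLN1 at 33.9, while the endothelial markers PECAM1 and CDH5 had medians of 0.192 and 0.161 CPM.

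The sets differed most in the genes of ciliated cells, which were lowest in set 3 and highest in set 6. DNAH5, a heavy chain of the outer dynein arm of motile cilia, stood at 22.2 ± 4.34 CPM in set 3, 305 ± 19.4 in set 6, and between 67.8 ± 8.04 and 124 ± 12.2 in the other sets (SD, n = 10 each). All 20 tested members of the ciliated cell list differed between the sets, over all genes and adjusted over the list alone. Of these, 19 were highest in set 6 and 20 lowest in set 3. Against their mean over the sets, the median member stood at −2.18 (log2) in set 3, −0.38 in set 5, −0.13 in set 1, 0.12 in set 2, 0.74 in set 4 and 1.80 in set 6. MCIDAS, a regulator of multiciliated cell fate, was the member that was highest in set 2 rather than in set 6.

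**Figure D1:**
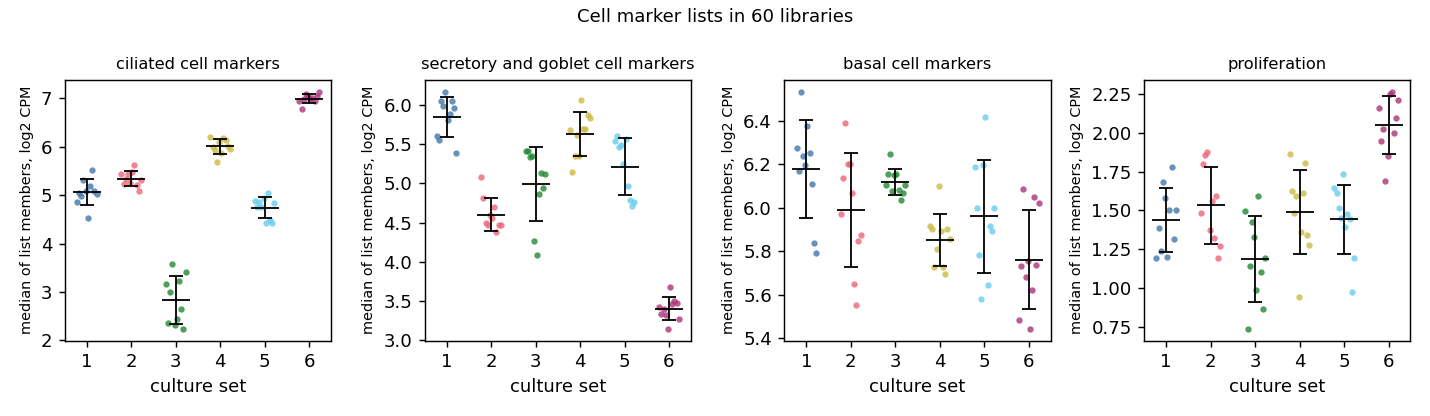
Median level (log2 CPM) of the members of 4 marker lists in each of 60 libraries, by culture set on the horizontal axis; points are libraries and bars the mean ± SD of 10 libraries. Ciliated cell markers were lowest in set 3 and highest in set 6, secretory and goblet cell markers lowest in set 6, and proliferation genes highest in set 6.

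The adjusted p of DNAH5 over the sets was 3.8e-41, and 97.4% of the variance of its log2 level lay between sets. CCDC39, needed to assemble the inner dynein arms, ran from 2.96 ± 0.867 CPM in set 3 to 61.9 ± 6.52 in set 6, but a gene on the other strand that overlaps it had 401% of its counts, and the labels do not say whether strand was used in counting. With the other sets as the reference, the ciliated cell list was lower in set 3 (20 members lower, camera adjusted p = 2.1e-55) and higher in set 6 (19 members higher, adjusted p = 3.0e-37). Both calls held with an estimated correlation between members, at adjusted p = 0.000102 and 0.00259. It was also called higher in set 4 (19 members) and lower in set 5 (16 members), with adjusted p = 0.0742 and 0.63 with an estimated correlation. The share of mitochondrial ribosomal RNA was highest in set 6 as well, as given above.

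Secretory and goblet cell genes followed another order of sets. SCGB1A1 was highest in set 4, at 210.3 ± 21.6 CPM, and lowest in sets 6 and 2, at 19.8 ± 4.45 and 23.5 ± 2.92 (SD, n = 10 each). BPIFA1 stood at 7641 ± 752 and 7782 ± 453 CPM in sets 1 and 2 and at 1162 ± 179.9 in set 6. MUC5AC, the gel-forming mucin of goblet cells, ranged between 6.13 ± 4.64 CPM in set 1 and 0.114 ± 0.126 in set 6. All 17 tested members of the secretory and goblet cell list differed between sets, over all genes and adjusted over the list alone. Their median stood highest in set 1 (0.99, 13 members higher than in the other sets) and lowest in set 6 (−0.83, 13 lower), with camera adjusted p = 4.8e-07 and 0.0014. With an estimated correlation these became adjusted p = 0.0643 and 0.354. The list was also called higher in sets 4 and 5 (9 members higher and 2 lower in each), with adjusted p = 0.292 and 0.63 with an estimated correlation.

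Basal cell markers varied less between sets than ciliated or secretory markers, with medians from −0.36 in set 6 to 0.38 in set 3. Of 20 tested members, 18 differed between sets, both over all genes and adjusted over the list alone. KRT5 was highest in set 3 (646 ± 81.0 CPM) and lowest in set 5 (172 ± 32.6), and KRT14 was highest in set 3 (51.8 ± 7.75) and lowest in set 4 (4.83 ± 2.24; SD, n = 10 each). The list was called higher in sets 1 and 3 and lower in set 6, with adjusted p = 0.396, 0.337 and 0.555 with an estimated correlation. Of 13 squamous and wound keratinocyte markers, 13 differed. KRT13, a keratin of stratified epithelium, was highest in set 3 (86.0 ± 14.3 CPM), whereas SPRR3, a cornified envelope precursor, was highest in set 6 (15.7 ± 6.74). This list was lower in set 4 by camera, with adjusted p = 0.661 with an estimated correlation.

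Genes of the cell cycle were highest in set 6. CENPF, a kinetochore protein of dividing cells, stood at 34.9 ± 3.78 CPM in set 6 and at 7.04 ± 1.61 to 13.7 ± 3.31 in the others, and TPX2, a spindle assembly factor, at 8.6 ± 1.44 against 2.00 ± 0.508 to 3.33 ± 0.274 (SD, n = 10 each). Of 19 proliferation genes, 18 differed between sets, and 15 were higher in set 6 than in the other sets. The median member lay at 0.89 in set 6 and at −0.34 in set 3. The list's higher level in set 6 and lower level in set 3 had adjusted p = 0.555 and 0.883 with an estimated correlation.

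Markers of other cell types gave few testable genes. Of 14 ionocyte and neuroendocrine markers 3 were tested and 3 differed, among them FOXI1, the ionocyte transcription factor, at 2.19 ± 0.441 CPM in set 1 and 0.761 ± 0.264 in set 6. Of 20 immune cell markers 3 were tested and 3 differed. Among them CD4 had the order of sets of the ciliated cell median, with 9.32 ± 0.934 CPM in set 6 and 0.974 ± 0.263 in set 3, and LYZ, lysozyme of glands and macrophages, was highest in set 6 at 5.62 ± 0.966. Camera called this list higher in set 6, with adjusted p = 0.168 with an estimated correlation. That call rests on the 3 tested members, and the pan-leukocyte gene PTPRC reached at most 0.308 CPM in any library. Of 15 fibroblast and endothelial markers 5 were tested and 5 differed. FBLN1, a matrix glycoprotein, ranged from 16.7 ± 2.95 CPM in set 6 to 59.3 ± 16.94 in set 3, and COL1A1, a chain of type I collagen, from 0.869 ± 0.229 in set 6 to 3.68 ± 1.64 in set 1 (SD, n = 10 each).

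**Figure D2:**
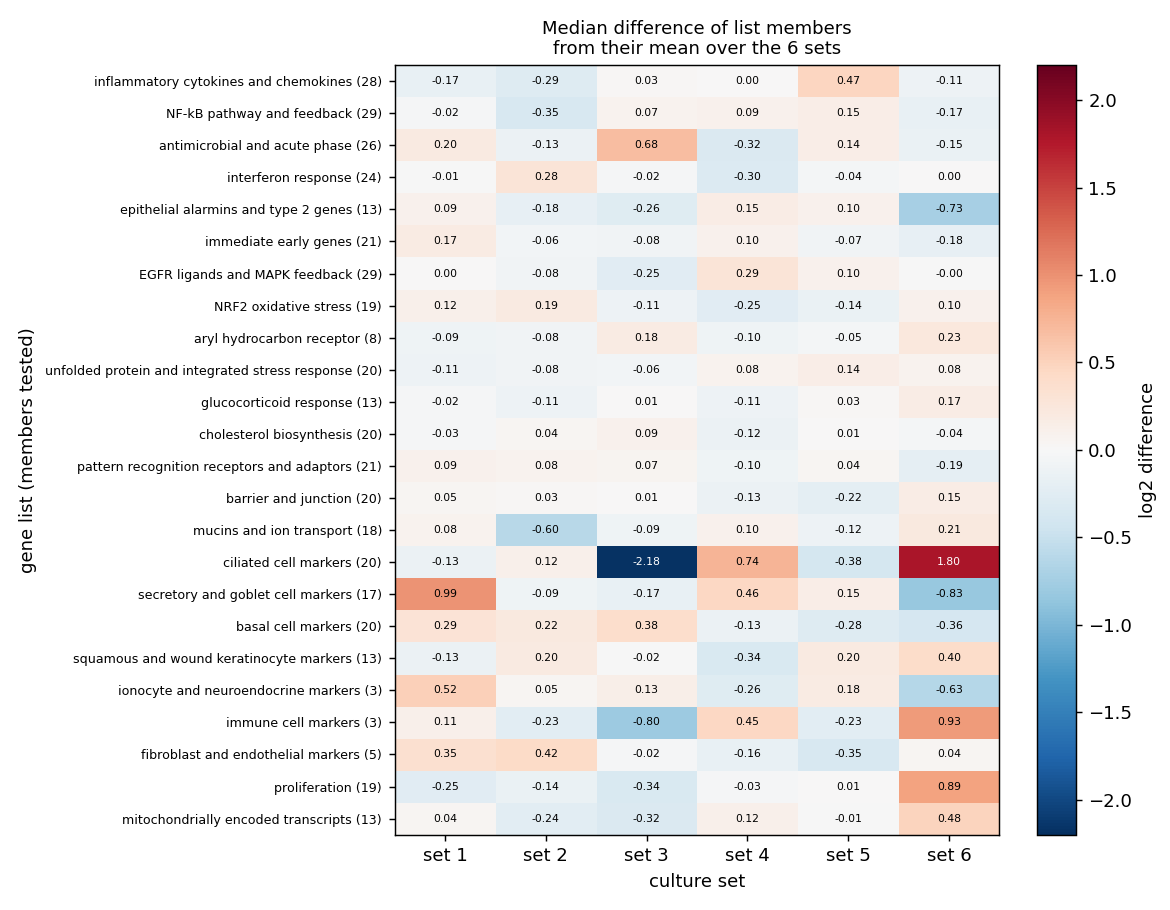
Median log2 difference of the members of 24 gene lists (vertical axis, with the number tested) from their mean over the 6 culture sets (horizontal axis); colour and printed numbers give the log2 difference. The ciliated cell list has the widest range, from −2.18 in set 3 to 1.80 in set 6.

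Antimicrobial genes and mucins differed in nearly all members. LTF, the iron-binding lactoferrin, ran from 2.08 ± 1.37 CPM in set 1 to 47.8 ± 18.2 in set 5. ITLN1, an intestinal and airway lectin of the alarmin and type 2 list, stood at 34.5 ± 6.52 CPM in set 3 and 18.6 ± 4.17 in set 5, and between 0.31 ± 0.138 and 2.52 ± 0.641 in the other sets. MUC13, a membrane mucin, stood at 23.5 ± 4.92 CPM in set 6 and at 0.444 ± 0.22 to 3.44 ± 1.53 in the others, and MUC16, another one, at 1390 ± 473 and 1284 ± 448 in sets 4 and 6 and 179.5 ± 76.8 to 402 ± 224 in the others (SD, n = 10 each). Of 26 antimicrobial and acute phase genes 25 differed, with the highest median in set 3 (0.68). Of 18 genes of mucins and ion transport 18 differed, with the lowest median in set 2 (−0.60). Camera called the antimicrobial list higher in sets 3 and 5 and the mucin list lower in set 2. With an estimated correlation the adjusted p values were 0.972 in set 3, 0.972 in set 5 and 0.337 in set 2.

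**Figure D3:**
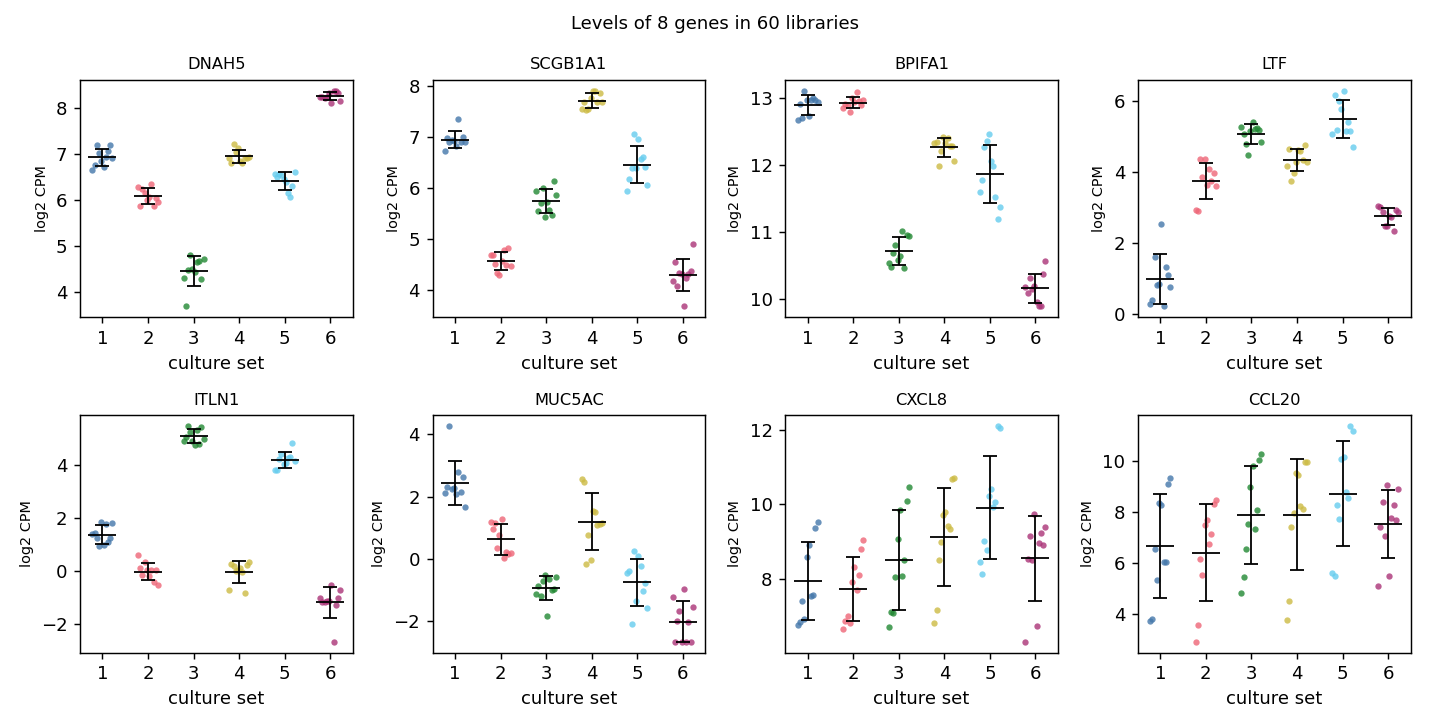
Levels (log2 CPM) of 8 genes in each of 60 libraries, by culture set on the horizontal axis; points are libraries and bars the mean ± SD of 10 libraries. DNAH5 and ITLN1 have 97.4% and 97.6% of their variance between sets, and CXCL8 and CCL20 have 29.4% and 15.7%.

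Cytokines and chemokines spread widely among the libraries within a set. CXCL8, the neutrophil chemokine, stood at 1481 ± 1533 CPM in set 5 and 248 ± 147.8 in set 2, and CCL20, which attracts dendritic cells and Th17 cells, at 865 ± 942 in set 5 and 144 ± 121 in set 2 (SD, n = 10 each). Their adjusted p values over the sets were 2.6e-05 and 0.00915. The colony-stimulating factor CSF3 did not pass (adjusted p = 0.0511, highest in set 5 at 23.6 ± 24.8 CPM), nor did TNF (adjusted p = 0.329). With the library block of the authors' subset tables as a term both passed, at adjusted p = 2.1e-08 and 0.000965, and CSF3 also with DESeq2's size factors, at adjusted p = 0.0471. IL1B passed with 22.2 ± 21.9 CPM in set 5 and 6.65 ± 2.05 in set 2 (adjusted p = 0.0125). IL6 passed with 1.80 ± 1.74 CPM in set 5, 1.45 ± 0.714 in set 2 and 0.114 ± 0.108 in set 6 (adjusted p = 1.4e-06). Its mean log2 level was highest in set 2, and genes on the other strand overlap it. Of 28 tested members of the list, 21 differed between sets over all genes and 19 adjusted over the list alone. Those with the smallest p were CX3CL1, a membrane-bound chemokine, at 75.6 ± 29.4 CPM in set 1 and 11.7 ± 4.19 in set 6, and CCL28, a mucosal chemokine, at 36.2 ± 3.18 in set 6 and 16.4 ± 3.77 in set 2. In the other 23 lists, the count adjusted over the list alone equalled that over all genes.

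The NF-kB list had 19 of 29 members that differed. REL, an NF-kB subunit, was highest in set 4 (45.3 ± 7.21 CPM) and lowest in set 2 (25.7 ± 1.16), and BCL3, a nuclear partner of NF-kB, was highest in set 1 (9.27 ± 1.44) and lowest in set 6 (4.83 ± 1.20; SD, n = 10 each). Of 24 interferon response genes 23 differed. IFI27, an interferon-induced mitochondrial protein, stood at 43.7 ± 10.02 CPM in set 2 and at 6.49 ± 2.26 to 13.3 ± 3.71 in the others, and MX2, an antiviral GTPase, was highest in set 6 (19.7 ± 1.71). The interferon list was higher in set 2 (15 members) and lower in set 4 (15 members), with adjusted p = 0.337 and 0.515 with an estimated correlation. Immediate early genes differed in 19 of 21 members, with CTGF, a matrix-associated growth regulator, at 129 ± 20.6 CPM in set 6 and 7.53 ± 2.63 in set 3, and NR4A2, an orphan nuclear receptor, highest in set 4 (13.6 ± 3.65). Of 29 genes of epidermal growth factor ligands and kinase feedback 24 differed, with BTC, a ligand of that receptor, highest in set 6 (17.5 ± 2.47) and ITGA2, a collagen-binding integrin, highest there too (290.4 ± 49.1).

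The list of epithelial alarmins and type 2 genes was called higher in set 5, with 7 members higher and 3 lower and a median of 0.40 against the other sets (camera adjusted p = 0.0035). This call held with an estimated correlation, at adjusted p = 0.0142. Against their mean over the sets, however, the median member was highest in set 4 (0.155), at 0.1 in set 5, and furthest from the mean in set 6 (−0.728). All 13 tested members differed between sets, over all genes and adjusted over the list alone. Apart from ITLN1, the smallest p was that of SERPINB10, at 28.2 ± 4.17 CPM in set 6 and 2.56 ± 0.505 in set 3. A gene on the same strand that overlaps SERPINB10 had 340% of its counts, so its level is uncertain. TSLP and IL33, epithelial cytokines that act on innate lymphoid cells, were highest in set 3 (5.56 ± 1.09 CPM) and set 4 (14.5 ± 3.79), and lowest in set 2 (2.35 ± 0.545) and set 6 (3.92 ± 0.951; SD, n = 10 each).

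Transcripts of receptors for bacterial products were found in each set, but LY96 and CD14 were low beside TLR4. TLR4, the signalling receptor for LPS, stood between 14.8 ± 3.30 CPM in set 6 and 30.3 ± 6.11 in set 4, its partner LY96 between 0.644 ± 0.237 in set 6 and 1.90 ± 0.405 in set 3, and the co-receptor CD14 between 0.737 ± 0.34 in set 6 and 4.75 ± 1.40 in set 1 (SD, n = 10 each). All 3 passed, with adjusted p = 5.9e-06, 4.1e-08 and 9.3e-16. LBP, which hands LPS to CD14, stood at 5.42 ± 3.13 CPM in set 5 and at most at 0.158 ± 0.0563 in the other sets, and F2R, a thrombin receptor, was highest in set 2 (10.9 ± 2.50). Of 21 pattern recognition receptors and adaptors 20 differed between sets.

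Most members of the stress and metabolic lists differed between sets. All 19 genes of the NRF2 list differed. NQO1, a quinone reductase, was highest in set 6 (265 ± 14.1 CPM) and lowest in set 3 (66.9 ± 5.91), and GCLC, which starts glutathione synthesis, was highest in set 6 (326 ± 44.5). The list's lower level in set 4 had adjusted p = 0.555 with an estimated correlation. Of 8 aryl hydrocarbon receptor genes 7 differed, among them LRAT, an acyltransferase that forms retinyl esters, highest in set 5 (4.62 ± 1.55 CPM), and NFE2L2, which encodes NRF2 and is overlapped by genes on the other strand, highest in set 6 (288 ± 14.4). Of 20 genes of the unfolded protein and integrated stress response 18 differed, with ASNS, asparagine synthetase, highest in set 5 (22.4 ± 4.17) and PSAT1, a serine synthesis enzyme, highest in set 6 (16.3 ± 2.26; SD, n = 10 each). The list was called higher in set 5, with adjusted p = 0.555 with an estimated correlation.

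Of 13 glucocorticoid response genes 11 differed, with FKBP5, a chaperone of the glucocorticoid receptor, highest in set 6 (23.0 ± 2.87 CPM) and TFCP2L1 highest in set 5 (131 ± 44.9). Of 20 cholesterol biosynthesis genes 19 differed, with SQLE, squalene epoxidase, highest in set 6 (70.6 ± 5.28), as was IDI1 (56.0 ± 8.48). Barrier and junction genes differed in 18 of 20 members, with PKP1, a desmosomal plaque protein, highest in set 1 (34.2 ± 5.99) and DSG3, a desmosomal cadherin, highest in set 6 (55.9 ± 8.84; SD, n = 10 each). This list was called lower in set 5, with adjusted p = 0.567 with an estimated correlation. CFTR, the chloride channel of ionocytes and secretory cells, was highest in set 5 (23.8 ± 7.42) and lowest in set 6 (11.7 ± 1.54), although genes on the other strand overlap it. All 13 mitochondrially encoded transcripts differed, with MT-CO1 at 7090 ± 764 CPM in set 6 and 3779 ± 667 in set 2 and MT-ND2 at 148 ± 23.9 in set 6 and 49.2 ± 11.5 in set 3. This list was called lower in set 2, with adjusted p = 0.972 with an estimated correlation.

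Across all genes, 13003 of 14278 tested differed between the 6 sets in edgeR's quasi-likelihood test at an adjusted p under 0.05 (91.1%), and 4532 of these had over 2-fold between the highest and the lowest set. The median gene had a log2 range of 0.72 between sets and an SD of 0.27 within sets, and 49.8% of its variance lay between sets. Against the other sets, set 6 stood apart in the largest number of genes, 9535 (5044 higher, 4491 lower), of which 1302 were higher and 712 lower by over 2-fold. Set 3 had 6492 such genes (3268 higher, 3224 lower), with 194 higher and 920 lower by over 2-fold. Set 1 had 8124 (3883 higher, 4241 lower), set 2 7810 (4074 higher, 3736 lower), set 4 6374 (3434 higher, 2940 lower) and set 5 7824 (3707 higher, 4117 lower). Over 24 lists and 6 sets, camera made 25 calls with a preset correlation, 3 with an estimated one, and fry made 80.

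The positions of the leading genes in the GRCh38 annotation are these. DNAH5 (ENSG00000039139) lies on chromosome 5 from 13690331 to 13944543, ITLN1 (ENSG00000179914) on chromosome 1 from 160876539 to 160885170 and SCGB1A1 (ENSG00000149021) on chromosome 11 from 62405103 to 62423195. BPIFA1 (ENSG00000198183) lies on chromosome 20 from 33235995 to 33243311 and CXCL8 (ENSG00000169429) on chromosome 4 from 73740506 to 73743716. The values are counts over whole genes.

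The title codes come in 2 forms, one shared by sets 2, 3 and 5 and the other by sets 1, 4 and 6, and the authors' subset tables keep these sets together. Ciliated cell genes had a median log2 difference of −1.56 between the first and the second form, with DNAH5 at −1.60 ± 0.56 (SE, 3 sets against 3). Against their mean over the sets, the median ciliated member stood at 0.118, −2.177 and −0.38 in sets 2, 3 and 5. In sets 1, 4 and 6 it stood at −0.126, 0.745 and 1.803, so the forms overlapped. Mitochondrially encoded transcripts had a median difference of −0.46 between the forms. No gene of any list passed over all genes. Adjusted over the list alone, 5 mitochondrially encoded transcripts and 1 gene of the alarmin and type 2 list passed, and none in the other 22 lists. Camera with a preset correlation called 9 lists. The ciliated cell (adjusted p = 1.4e-16) and mitochondrial (3.8e-07) lists were lower, and so were mucins (0.0149), proliferation (0.0223), immune cell markers (0.0408) and immediate early genes (0.0436), while antimicrobial genes (0.0359) and basal and squamous markers (0.0408 each) were higher. None held, with adjusted p = 0.674 with an estimated correlation as the lowest of the 9 and 0.811 as the highest. Over 17793 genes tested with counts summed per set, edgeR's quasi-likelihood test called 0, while 962 had an unadjusted p under 0.05 and DESeq2 called 34. The labels do not say what the forms stand for.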

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

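The splits of the samples and the tests of the share of ciliated cells and of total counts and mitochondrial ribosomal RNA were chosen after the results were seen; the test of length was written before its result.

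In Dixon's test, the highest or lowest library of a set stood far from the others in 12 of 246 groups, in 10 libraries. Chance gives about 1 in 20 groups where the 10 libraries of a group are alike. Each group held 2 libraries of each of the 5 library blocks described below, so that rate need not hold here. In set 1, the total of library 10 was 15862121 against 12370063 for the next library. Library 3 of that set had the highest median of mitochondrially encoded transcripts, 9.012 log2 CPM against 8.509, and the highest MUC5AC level, 19.02 CPM against 6.699. Library 1 of set 1 had the lowest immune cell marker median, 0.594 against 1.116, and the highest TSLP level, 8.011 CPM against 5.54. In set 2, IL33 stood at 19.95 CPM in library 19 against 13.33 in the next, and TNF at 1.531 in library 20 against 0.7096. The ionocyte and neuroendocrine median was −1.058 in library 30 of set 3 against −0.016. In set 4, library 31 had a barrier and junction median of 6.122 against 5.817 and library 32 a squamous marker median of 1.236 against 1.927. In set 5, library 46 had a fibroblast and endothelial median of 1.664 against 0.833, and in set 6 library 51 had a median of pattern recognition genes of 3.848 against 3.468. Of these libraries, 1, 31, 32 and 51 belong to block A and 10, 19, 20 and 30 to block E. Library 3 belongs to block B and library 46 to block C. No explanation of these single values, the block included, was tested.

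The ciliated cell genes, lowest in set 3 and highest in set 6, were weighed against technical sources. With the trend of level with exon length removed, the list median still ranged over 4.07 (log2) between sets, against 3.98 without the correction, which argues against a length bias. With log2 total counts and the share of mitochondrial ribosomal RNA as terms, the list median ranged over 4.06, and its members differed between sets 6 and 3 by 0.91 to 5.09 with an SE of at most 0.24, which argues against these as the whole source. That 19 of 20 members were highest in set 6 and lowest in set 3 is the observation itself and decides nothing on the share of ciliated cells, since a change per cell can give it too. In the 10 libraries of set 3 the list median was 2.24 to 3.58 log2 CPM, and in those of set 6 it was 6.77 to 7.13. Each set holds 2 libraries of each of the 5 library blocks described below. These values, read after the results were seen, thus argue against the block as the source. A different share of these cells, a difference in expression per cell, in culture age or in the origin of a set stays open. So does a stimulus that does not follow the blocks, since no library's stimulus is named.

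Other groupings of the 60 libraries into sets of 10 were compared with the real one. For the test over 6 sets, 1 of 40 groupings, the real one, gave as many genes, 13003 against at most 1295 in the others. Libraries of a set thus resembled each other more than those of the random groups did. The groupings move single libraries, so they do not test chance differences between the origins of the sets. For each set against the others the real grouping was also the only one of 40 (1 in each case). The real counts and the highest of the others were 8124 and 1 for set 1, 7810 and 0 for set 2, 6492 and 961 for set 3, 6374 and 2 for set 4, 7824 and 1 for set 5, and 9535 and 3179 for set 6. For the 2 forms of title code the 10 splits of 6 sets are too few for a share under 0.05. The real split gave 0 genes, all 10 gave as many, and another gave 1621; what sets those groups apart was not tested.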

How the results depend on the processing

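The alternatives for DESeq2, size factors and filtering over the 6 sets, and those for gene lists, were planned; all others were chosen after the data were seen. The count of 13003 genes over the sets lay between 13033 and 15493 under the alternatives that keep its threshold, and those of single sets stayed within 1.5 times. With over 2-fold required as well it was 4532. Of 25 list calls by set an estimated correlation left 3, and fry made 80. Named genes kept their side of the threshold in 292 of the values recomputed between sets. Exceptions were CSF3, past it with DESeq2's size factors and with the block as a term, and TNF with the block. For the forms of title code, DESeq2 called 34 genes, and leaving out a set gave 0 to 1 (1 without set 2).

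Between blocks, the counts moved as follows, and the cause was not tested except where fewer samples or a stricter rule give it. With DESeq2's size factors, D against B gave 1 gene and E against C 1. With no filter E against C gave 49, with DESeq2 276, and without mitochondrial ribosomal and RN7 genes 1. With single libraries, which treat both libraries of a set and block as separate, C against B gave 2077, D against B 230, E against C 1997 and E against D 3450. With at least 1.5-fold required, A against B gave 924, C against B 329, D against B 0, E against B 843 and E against D 560. With the length trend removed, D against B gave 0 by limma (2 without the correction) and E against C 1 (1 without it, so the tool moved this count). Leaving out a set gave 1970 to 2792 for A against B, 344 (without set 4) to 1129 for C against B, 0 to 4 for D against B, 2677 to 4691 for E against B, 0 to 769 (without set 6) for E against C and 985 (without set 1) to 2080 for E against D. Of 47 list calls an estimated correlation left 10. Calls of named genes were lost in 38 recomputed values for A against B, 67 for C against B, 65 for E against B and 32 for E against D, most with no set term.

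The set is the replicate block of these fits. With no replicate block, A against B gave 701 genes, C against B 30, D against B 0, E against B 367 and E against D 199. The labels number the libraries apart in each set, so between sets the library block was the only pairing; with it as a term 13860 genes differed over the sets and 7861 (set 3) to 10511 (set 6) for single sets. The alternatives foreseen for LPS and HDM and for responses between sets were not run, since no library's stimulus is named. Those for normalised values were not run either, nor were list tests without each set or without the block. At these depths, genes changed 1.5-fold were recovered in 67.2% of cases over the sets in simulated data without block differences, so smaller differences can be missed. In the real data, which hold block differences, that share may be lower.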

Other observations

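All comparisons between blocks, the splits of their samples and the tests of neighbouring numbers were chosen after the files were seen; the tests of length, of depth and of low oxygen were written before their results.

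The authors' subset tables keep the same 2 libraries of each set together, which gives 5 blocks of 12 libraries, called A to E here. The labels put no library in such a group and name no block's stimulus, so no condition is read into them. The liquids that the labels name (LPS, HDM, both or the vehicle) are fewer than the 5 blocks. The blocks thus cannot each stand for a different one of these liquids. Counts were summed per set and block and tested with edgeR with the set as a term, for the 6 pairs of blocks that share a table of 24 libraries. Over all 5 blocks, 6672 of 15837 genes differed.

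Genes of the response to low oxygen were lower in block A than in block B. EGLN3, an oxygen-sensing prolyl hydroxylase, differed by −3.79 ± 0.09 (log2, SE), PFKFB4, a regulator of glycolysis, by −3.83 ± 0.13, NDRG1 by −2.43 ± 0.17, SLC2A1, the glucose transporter GLUT1, by −2.30 ± 0.15, and VEGFA, the angiogenic growth factor, by −2.06 ± 0.15, each lower in 6 of 6 sets. The largest decreases were FLT1, a VEGF receptor, at −4.46 ± 0.15, EDN2, an endothelin, at −4.41 ± 0.21 and ANGPTL4 at −4.27 ± 0.29. ANGPTL4 is also a member of the fixed glucocorticoid list, whose lower call is given below. The largest increases were CYP1B1, a target of the aryl hydrocarbon receptor, at 2.66 ± 0.18, PTGFR, a prostaglandin receptor, at 2.63 ± 0.16 and OASL, an interferon-induced gene, at 1.94 ± 0.18. In edgeR 2707 genes differed (1324 higher, 1383 lower in A), of which 59 were higher and 300 lower by over 2-fold. Of the fixed lists, cholesterol synthesis (9 higher, 11 adjusted over the list alone) and the aryl hydrocarbon receptor list (4 higher, 1 lower, 6 adjusted over the list alone) were called higher, at adjusted p = 0.0255 and 0.0405 with an estimated correlation. NF-kB genes were lower (17 of 30, 18 adjusted over the list alone), with adjusted p = 0.204 with an estimated correlation. Camera also called cytokines lower (1 higher, 10 lower, 15 adjusted over the list alone), glucocorticoid genes lower (4 higher, 6 lower, 10 adjusted over the list alone) and interferon genes higher (8 higher, 0 lower, 11 adjusted over the list alone), with adjusted p = 0.419, 0.167 and 0.296 with an estimated correlation.

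Cytokines and NF-kB genes were higher in blocks C and E than in block B, and higher in E than in D. In E against B, CCL20 differed by 2.64 ± 0.24 (log2, SE), CXCL8 by 2.16 ± 0.23, TNF by 2.70 ± 0.31, IL6 by 2.05 ± 0.33, and CSF3 by 3.40 ± 0.36, each higher in 6 of 6 sets. IL17C, an epithelial cytokine, had the largest increase at 3.63 ± 0.35, followed by CSF3 and CD83, at 3.37 ± 0.31. Of 29 cytokines tested, 25 were higher (25 adjusted over the list alone) and 0 lower, with a median of 2.14, and of 30 NF-kB genes 25 were higher (26 adjusted over the list alone), at adjusted p = 0.000606 and 0.0191 with an estimated correlation. In C against B, 24 cytokines (25 adjusted over the list alone) and 22 NF-kB genes (25) were higher, at adjusted p = 0.000359 and 0.00553 with an estimated correlation, and so were 11 of 27 antimicrobial genes (14 adjusted over the list alone), at adjusted p = 0.0255 with an estimated correlation. In E against D both lists had 25 members higher (25 and 26 adjusted over the list alone), at adjusted p = 0.000359 and 0.00833 with an estimated correlation. Camera with a preset correlation called antimicrobial genes higher in E against B (15 higher, 18 adjusted over the list alone) and in E against D (13 higher, 15 adjusted over the list alone) as well, with adjusted p = 0.141 and 0.0701 with an estimated correlation. Squamous and wound keratinocyte markers were called higher in the same 3 comparisons, with medians of 0.53 in C against B, 0.44 in E against B and 0.38 in E against D and adjusted p = 0.137, 0.419 and 0.438 with an estimated correlation. So were the interferon, immediate early, growth factor, NRF2 and unfolded protein lists, with adjusted p = 0.0584 to 0.475 with an estimated correlation. In C against B ciliated cell markers and proliferation genes were called lower and basal markers higher, with adjusted p = 0.641, 0.196 and 0.438 with an estimated correlation. The largest decrease in E against B was FAM46C, at −1.48 ± 0.21. CXCL8 ranged from 79.5 to 350 CPM over the libraries of block A, 112 to 520 in B, 241 to 1357 in C, 188 to 1079 in D and 448 to 4395 in E. The blocks thus overlap when the sets are pooled, although CXCL8 was higher in E than in B in 6 of 6 sets.

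Gene counts over all genes were 890 for C against B (520 higher, 370 lower), 3870 for E against B (1983 higher, 1887 lower) and 1818 for E against D (1133 higher, 685 lower). Leaving out a set moved 2 of these by over 1.5 times: C against B gave 344 without set 4, 466 without set 5, 525 without set 3 and 570 without set 1, and E against D gave 985 without set 1, 1066 without set 4 and 1118 without set 3. D against B gave 2, FAT2, an atypical cadherin, at −0.50 ± 0.09 and MT-ATP8 at −0.46 ± 0.07, with 1302 at an unadjusted p under 0.05 and 3 by DESeq2. MT-ATP8 is uncertain, since a gene on the same strand that overlaps it had 500.6% of its counts. In D against B the mitochondrially encoded transcripts had a median of −0.34 (1 lower, 11 adjusted over the list alone, adjusted p = 0.0191 with an estimated correlation), and in E against B −0.30 (8 lower, 9 adjusted over the list alone, adjusted p = 0.419 with an estimated correlation). Camera called them lower in C against B and E against C too, with adjusted p = 0.475 and 0.687 with an estimated correlation. Their share of the counts fell with the title number in sets 1 to 5 (Spearman −0.83 to −1, 10 libraries each), where the blocks follow that order, against −0.13 in set 6. Over all sets, the median share of mitochondrial ribosomal RNA was also higher in D and E than in B (50.1%, 48.9% and 46.5%), but within sets it went both ways. In set 2 the libraries of D held 49.8% and 52.6%, against 44.0% and 45.2% in B. In set 4 those of D held 48.0% and 49.5%, against 50.7% and 52.9% in B. The lower level of mitochondrially encoded transcripts is not parted from order or from that share. E against C gave 0 in edgeR, with 3049 at an unadjusted p under 0.05, 276 by DESeq2 and 769 without set 6. Camera with a preset correlation called cytokines (median 0.57, 11 adjusted over the list alone) and NF-kB genes (median 0.12, 7 adjusted over the list alone) higher in E against C, with adjusted p = 0.172 and 0.591 with an estimated correlation, and cytokines higher in D against B (median 0.15, 1 adjusted over the list alone), with adjusted p = 0.52 with an estimated correlation. Barrier genes were called lower in both, mucins lower in D against B and basal markers lower in E against C, with adjusted p = 0.306 to 0.475 with an estimated correlation. Splits that swap the 2 blocks compared within sets were fitted to these blocks alone. Of 32 splits, only 1, the real one, gave as many genes for A against B (2240, at most 0 in the others) and C against B (764 and 2). The same held for E against B (1705 and 200) and E against D (1655 and 1). For E against C it was also 1 of 32 (4 and 0), but with 0 genes in the fit over all blocks nothing is read from these 4. A share of 1 in 32 is the lowest that 32 splits can give. With 6 comparisons chosen after the files were seen, chance is not excluded by it. For D against B the real split gave 0, so all 32 necessarily gave as many (107 in another), and the splits decide nothing there.

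That libraries of one block share levels was weighed against their place in the titles. In sets 1 to 5 the partner in a block always has the neighbouring title number, with median correlations of 0.247 to 0.654, so order and block cannot be told apart there. In set 6, where partners are not neighbours, 2 of 10 libraries correlated best with a neighbouring number and 5 with their table partner, but the median correlation with the partner was only 0.063, so a part of neighbouring title numbers stays open. Differences followed gene length most in D against B (Spearman −0.294 across genes, which are not independent replicates), where both calls by limma were lost with the trend removed (2 and 0), and less in E against B (−0.25), C against B (−0.185), E against C (−0.172), E against D (−0.106) and A against B (0.089). In E against B limma called 3439 genes with the trend removed, 2914 of them among the 3815 called without the correction, which argues against length as the whole source there; length in D against B and what the blocks stand for stay open.

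A hypothesis for the lower hypoxia genes in block A is a response to low oxygen in block B relative to A. A list of 32 such genes was written after the leading genes were seen, and 25 members that had not been seen were all lower (25 of 25), with a median of −1.31 and p = 2.3e-08 with an estimated correlation. With total counts and mitochondrial ribosomal RNA as terms 32 of 32 stayed lower, and with the length trend removed the list mean was −1.764 against −1.745, which argues against depth and length. The list's median per library was taken over all 32 members, not over the 25 unseen ones alone. It thus rests in part on genes already seen to be lower in block A. This median was 4.40 to 4.87 log2 CPM in block A and 5.91 to 6.78 in blocks B to E. The 2 lowest libraries were those of block A in 6 of 6 sets. In set 6, where these are not neighbours, the higher of them lay 1.69 below the next library. For the list as a whole, this argues against neighbouring title numbers. In these medians block A lay below blocks C, D and E as well, so the pattern is not particular to block B. The response may be to oxygen or to another cue that acts on the same genes. The labels name 250 µl of apical liquid for 4 h, but tie no liquid or other cue to a block, so the cue stays open. Several members overlap other genes (ANKRD37, LOX, CA9, P4HA2, FAM162A).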
